A study of Homo sapiens with 12 samples.

How the data were processed

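The series holds 12 RNA sequencing libraries of primary human neuronal progenitors, 6 infected with a SOX5 lentivirus and 6 with a GFP control lentivirus, taken 14 days after infection at a multiplicity of infection of 10. Per the labels' protocols, libraries were made from 100 ng of total RNA with a stranded total RNA kit and ribosomal RNA depletion and were sequenced as 50-bp read pairs. The aligned bases per aligned read in the deposited metrics came to about 69.0, more than that read length, and the difference stays open. Per the submitters' processing notes, TopHat2 2.07 and HTSeq were used with build GRCh37. The strand setting of the counting is not given in the sources used here, so reads of overlapping antisense genes cannot be told apart. The deposited count table gives whole read counts per gene over the union of exons, without normalization, for 13099 genes. Genes with low counts are mostly absent from it, and the filter behind this is not given in the sources used here.

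The deposited RPKM table holds log2 values for 13054 genes. How the authors computed RPKM is not given in the sources used here. Per-sample files, 12 in number, held the same values as its columns and were not used. An alternative on counts from those files therefore gave no value. A deposited sheet of sequencing metrics, with alignment counts of reads and bases, fraction and ratio values and score values of the authors' components, was used for covariates and for tests of library quality. The sheet names no sequencing batch, so an alternative with the batch as a factor was not run.

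Gene symbols were looked up by identifier: 12484 came from a gene name table, 17 more from GENCODE 29, and 598 identifiers had none. GENCODE 29 describes build GRCh38, which differs from the build of the files, so it was used only for names and for the length and GC content of transcripts, known for 12790 genes. No coordinates are given for that reason. One list symbol, DDX58, was matched to its current name RIGI after the data were examined.

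Libraries were grouped by their labels. Counts as deposited were scaled with TMM, filtered with edgeR's filterByExpr defaults (a minimum count of 10 and a minimum total of 15), which left out 507 genes and kept 12592, and fitted with edgeR 4.0.16 (glmQLFit, robust, and glmQLFTest) in R 4.3.3 with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method, and genes under 0.05 were called. The SE of a log2 fold change was taken as its size over the square root of the F statistic. CPM values use TMM-scaled library sizes. The total count per library ran from 3144776 to 5802222. Common dispersion was 0.00742, a biological coefficient of variation of 8.62%. No pair of libraries within a group was close enough to be a copy: chi-square per gene lay between 2.14 and 10.8 over 11161 genes with a mean count of at least 20, where sampling noise gives about 1.

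Gene lists, 33 in all, were written from textbook knowledge before the data were examined, including markers of other cell types. They hold 1213 entries, of which 1002 are in the count table. Members absent from it or filtered out were not tested, so the counts called refer to tested members only. Tested were 11 of 22 oligodendrocyte lineage, 22 of 50 interferon response and 8 of 25 endothelial and pericyte genes. For fibroblast, cartilage and SOX family genes these were 10 of 24, 10 of 25 and 8 of 18. For each list the members called were counted, over all genes tested and adjusted over the list alone. The list was also tested with camera from limma 3.58.1 (preset correlation 0.01, adjusted over the 33 lists), and again with an estimated correlation. Camera asks whether the members differ from other genes. Fry asks whether the members move, on balance, one way, and does not compare them with other genes. The rule for named genes was also set before the data were examined. It names SOX5, then the 8 higher and 8 lower genes with the smallest p-value among called genes with a mean of at least 1 CPM, then the 4 higher and 4 lower genes with the largest fold change among those left. From each list up to 4 members with the smallest p-value could be named. Genes without a symbol and genes of the sex chromosomes that mark sex were skipped. A few further members were named after their values were seen, and the text says so. Some genes that the rule names are not reported here.

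The scripts were tested on simulated data with known answers. Counts were drawn for the real genes with 200 of them changed, in the design of 6 against 6 libraries, and 12396 genes were tested. A change of 1.5-fold was recovered in 78.0% of genes, 2-fold in 98.0%, 4-fold in 100% and a decrease to 0.5 of the level in 89.4%. There were 9 false calls, 4.76% of all calls. A list of 20 genes raised together was recovered and 0 of 19 unchanged lists were called by camera. Genes were drawn independently of each other, so this does not test camera on lists whose genes are correlated. The 200 changed genes are far fewer than the 3657 called in the real data. Scaling and false calls under so broad a change were therefore not tested.

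Alternatives were other normalizations (RLE and upper quartile), other filters on low counts (none, or at least 1 CPM in at least 6 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, the first principal component of 31 sequencing metrics, and 1 surrogate variable from sva 3.50.0. Limma-trend was also run on the RPKM values. Because the deposited RPKM values are on a log2 scale, they were converted back before pseudocounts of 0.1 and 1 were added, and fold changes there are on the log2(value + pseudocount) scale. The filter of at least 0.5 RPKM in at least 6 libraries removed none of the 13054 genes. Alternatives chosen after seeing the data were the authors' sequencing components as covariates, the 5' to 3' coverage ratio as a covariate, offsets for GC content and length, the deposited log2 values as they are, and the fit without 3 libraries far from their group on the second or the third principal component. Sequencing metrics were compared between groups with two-sided exact permutation tests in scipy 1.17.1.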

Results

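RNA from primary human neuronal progenitors of the developing cortex was sequenced after lentiviral infection with a SOX5 construct or with a GFP control vector. SOX5 is a transcription factor of the SOX family that acts in the specification of deep-layer cortical neurons. The virus was added when the cells were plated, with 10 infectious particles per cell (the multiplicity of infection), and RNA was taken 14 days later. Each group held 6 libraries, 12 in all, and the values are read counts per gene. The labels do not say whether the 6 libraries of a group came from separate cultures or donors, so the p-values measure only the spread between these libraries, which may be technical. Total counts ran from 3144776 to 4701195 in the control libraries and from 3877214 to 5802222 in the SOX5 libraries, with a median of 4671224 over all 12. Such totals leave genes below about 1 CPM with only a few reads per library. MT-RNR2, the large ribosomal RNA of mitochondria, took 8.23% of the counts on average.

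The overexpressed gene was checked first. SOX5 (ENSG00000134532.11) stood at 225 ± 10.2 CPM in the controls and 4318 ± 813 CPM with SOX5 (mean ± SD, n = 6 per group). Its level was 19.2-fold higher, a log2 fold change of 4.26 ± 0.134 (SE), with an adjusted p of 5.74e-10 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Single libraries ranged from 207 to 235 CPM in the controls and from 3128 to 5357 CPM in the SOX5 group, so all 12 libraries matched their labels. A two-sided exact permutation test of the log2 CPM values gave p = 0.00216, the smallest value that 6 against 6 libraries allow. Reads of the vector and of the cell's own SOX5 gene cannot be separated in counts per gene.

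The comparison asks which transcripts differ in progenitor cultures that carry additional SOX5. Genes of radial glia, of dividing cells and of the glial lineages were lower with SOX5, and genes of GABAergic interneurons were higher. The strongest evidence for a decrease was at SLC1A3 (ENSG00000079215.9), the glial glutamate transporter GLAST, with 390 ± 12.2 CPM in the controls and 60.0 ± 7.65 CPM with SOX5 (mean ± SD, n = 6 per group). The strongest evidence for an increase was at IGFBP5 (ENSG00000115461.4), a secreted binding protein for insulin-like growth factors, with 59.0 ± 7.11 CPM in the controls and 198 ± 17.1 CPM with SOX5. Of 12592 genes tested, 1825 were higher and 1832 were lower at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Decreases were larger: 447 genes fell at least 2-fold and 131 at least 4-fold, against 118 and 11 genes that rose as much. The median change was 1.33-fold among higher genes and 1.44-fold among lower genes. The groups did not overlap in 1814 genes, 14.4% of those tested, where chance gives 0.216%. The first principal component held 47.6% of the variance and separated the groups.

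**Figure D1:**
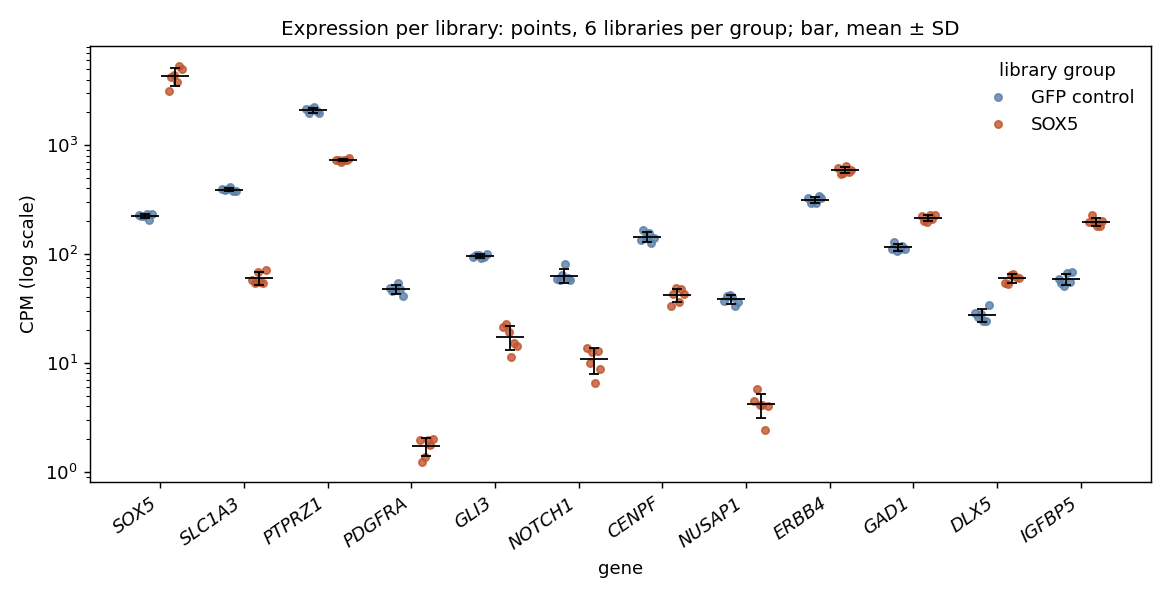
CPM values (log axis) of 12 genes in each of the 6 GFP control and 6 SOX5 libraries, with the mean and SD of each group as bars. The groups do not overlap for any gene drawn: SOX5, for example, lies between 207 and 235 CPM in the controls and between 3128 and 5357 CPM in the SOX5 libraries.

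Besides SLC1A3, the lower genes with the smallest p-values included PTPRZ1, PDGFRA, ZEB1, PTN, MOXD1 and VCAN. PTPRZ1, a receptor phosphatase of radial glia, fell by 1.53 ± 0.0409 on the log2 scale (SE, n = 6 per group), and PTN, a secreted ligand of that receptor, fell by 1.72 ± 0.0615. ZEB1, a transcription factor of neural progenitors, fell by 1.69 ± 0.0554. MOXD1, a monooxygenase-like protein, fell by 2.11 ± 0.0867. VCAN, the matrix proteoglycan versican, fell by 1.06 ± 0.0434. The higher genes with the smallest p-values, after IGFBP5 at 1.75 ± 0.0705, were DLX6-AS1, ROBO2, CNTNAP2, RYR2, LRP1B, ERBB4 and TENM3. The long non-coding RNA DLX6-AS1 rose by 0.89 ± 0.0403, the axon guidance receptor ROBO2 by 0.78 ± 0.0393 and the adhesion molecule CNTNAP2 by 1.01 ± 0.0513. The calcium release channel RYR2 rose by 1.13 ± 0.0583, the lipoprotein receptor family member LRP1B by 0.94 ± 0.0513 and the teneurin TENM3 by 0.88 ± 0.0554. Adjusted p-values in edgeR's quasi-likelihood test ran from 1.85e-31 for SLC1A3 to 1.27e-16 for TENM3 over the 8 lower and 8 higher genes with the smallest p-values. Reads of DLX6-AS1 are uncertain, because it overlaps DLX6 and DLX5 and the strand setting of the counting is not given in the sources used here.

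The largest fold changes among the remaining genes with a mean of at least 1 CPM included those of genes with few reads in one group. TRPM8, a cold-sensing channel, had 134 reads over the 6 SOX5 libraries and 7 over the controls, 2 of which had none, a log2 fold change of 3.98 ± 0.417 (SE, n = 6 per group). PAPPA, a protease that acts on insulin-like growth factor binding proteins, had 144 and 13 reads (3.26). The collagen gene COL14A1 had 105 and 12 reads (2.90). In the other direction, the glial transcription factors OLIG2 and OLIG1 had 11 and 6 reads with SOX5 against 178 and 101 in the controls. Their fitted log2 fold changes were -4.06 and -4.05. PIMREG, a gene of mitotic cells, had 6 reads against 86 (-3.83), and ATP10B, a lipid transporter, had 13 against 156 (-3.63).

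Radial glia are the stem cells of the developing cortex. Of 33 radial glia genes tested, 29 fell and 4 did not pass the threshold, with 1 higher and 29 lower adjusted over the list alone. The median log2 fold change was -1.35 (adjusted p = 3.97e-86, camera over 33 lists, and adjusted p = 3.91e-05 with an estimated correlation). GLI3, a transcriptional effector of Hedgehog signalling, fell by 2.46 ± 0.0997 on the log2 scale (SE, n = 6 per group), from 96.1 to 17.4 CPM. Members outside the naming rule, chosen after their values were seen, included the fatty acid binding protein FABP7, which fell by 2.28 ± 0.0808, and PAX6, a regulator of progenitor identity, which fell by 1.17 ± 0.0766. The 4 that did not pass were CRYAB at 0.18, ID4 at -0.05, PHGDH at -0.17 and PROM1 at 0.11.

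Genes of astrocytes and of the oligodendrocyte lineage fell as well. Of 18 astrocyte genes, 15 fell, 1 rose and 2 did not pass, with 1 higher and 15 lower adjusted over the list alone. Their median was -1.17 (adjusted p = 4.8e-25, camera, and adjusted p = 0.000203 with an estimated correlation). The BMP antagonist CHRDL1, the glutamate transporter SLC1A2 and the membrane protein MLC1 fell, with log2 fold changes of -1.05 ± 0.0448, -0.75 ± 0.0496 and -1.58 ± 0.115 (SE, n = 6 per group). The gene that rose was CD44, an adhesion receptor, at 0.79, named after its value was seen. Of 22 oligodendrocyte lineage genes listed, 11 were tested. Of these, 7 fell, 1 rose and 3 did not pass, with 1 higher and 7 lower adjusted over the list alone. The median was -1.02 (adjusted p = 9.72e-11, camera, and adjusted p = 0.000847 with an estimated correlation). PDGFRA, the growth factor receptor of oligodendrocyte precursors, was 27.5-fold lower at 1.72 CPM, with 49 reads over the 6 SOX5 libraries against 1246 in the controls. SOX8 fell by 1.47 ± 0.168 on the log2 scale. GPNMB, a glycoprotein also made by macrophages, was the gene that rose, at 2.40, and was named after its value was seen.

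**Figure D2:**
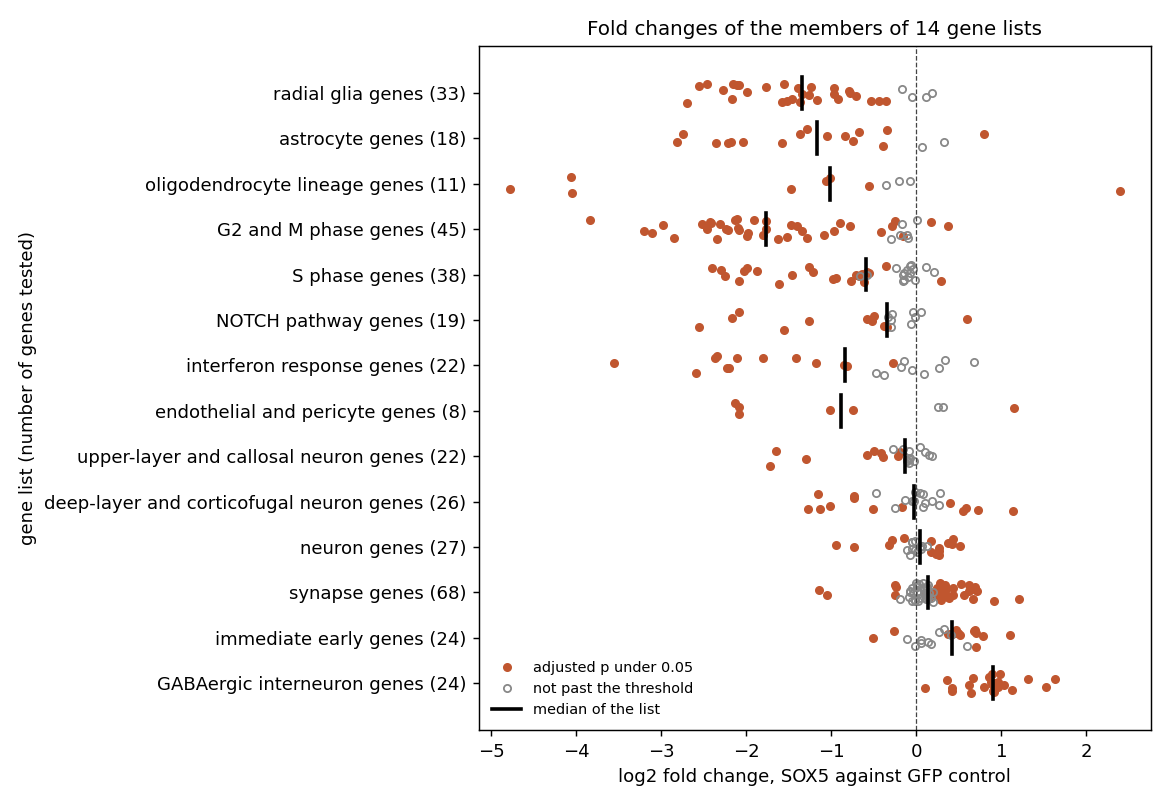
Log2 fold changes (SOX5 against GFP control) of the tested members of 14 gene lists, 1 point per gene, filled where the adjusted p of edgeR's quasi-likelihood test was under 0.05, with the list median as a black bar. The medians run from -1.77 for the genes of the G2 and M phases to 0.90 for the interneuron genes, and those of the neuron and deep-layer lists lie near 0.

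Genes of the cell cycle fell together with the progenitor genes. Of 45 genes of the G2 and M phases, 37 fell, 2 rose and 6 did not pass, with 2 higher and 41 lower adjusted over the list alone. Their median of -1.77 was the lowest of all 33 lists (adjusted p = 1.5e-36, camera, and adjusted p = 0.000193 with an estimated correlation). NUSAP1, a spindle protein, fell by 3.20 ± 0.141 on the log2 scale (SE, n = 6 per group), from 38.5 to 4.15 CPM. The kinetochore protein CENPF, the condensin subunit SMC4 and the spindle factor TPX2 fell with log2 fold changes of -1.77 ± 0.0812, -1.28 ± 0.0856 and -2.34 ± 0.173. The 2 genes that rose, named after their values were seen, were CTCF at 0.17 and GAS2L3 at 0.37. Of 38 S phase genes, 21 fell, 1 rose and 16 did not pass, with 2 higher and 24 lower adjusted over the list alone. The median was -0.60 (adjusted p = 7.2e-09, camera, and adjusted p = 0.0105 with an estimated correlation). RRM2, a subunit of the enzyme that makes deoxynucleotides, fell by 2.40 ± 0.160, and the thymidylate synthase gene TYMS fell by 1.46 ± 0.159. ATAD2 fell by 1.27 ± 0.131, and CENPU fell by 2.03 ± 0.229. The gene that rose was POLA1, a DNA polymerase subunit, at 0.29, named after its value was seen.

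GABAergic interneurons reach the cortex from the ventral forebrain, and their genes rose. All 24 members tested were higher, also when adjusted over the list alone. The median log2 fold change was 0.90 (adjusted p = 3.44e-26, camera over 33 lists, and adjusted p = 3.91e-05 with an estimated correlation). The neuregulin receptor ERBB4 stood at 316 ± 20.5 CPM in the controls and 590 ± 38.7 CPM with SOX5 (mean ± SD, n = 6 per group). GAD1, which makes GABA, rose by 0.90 ± 0.0573 on the log2 scale (SE), and the transcription factors MAF and DLX5 rose by 0.88 ± 0.0611 and 1.13 ± 0.0899. Reads of DLX5 and DLX6 are uncertain for the reason given for DLX6-AS1. Progenitor, glial and cell cycle lists were lower in the same libraries, with median log2 fold changes of -1.35, -1.17 and -1.77 for radial glia, astrocyte and G2 and M phase genes.

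Genes of excitatory cortical layers were mixed or lower. Of 22 genes of upper-layer and callosal neurons, 9 fell and 13 did not pass, with 0 higher and 9 lower adjusted over the list alone. Their median was -0.13 (adjusted p = 1.19e-06, camera, and adjusted p = 0.0158 with an estimated correlation). The transcription factors POU3F2 and LHX2 fell, with log2 fold changes of -0.58 ± 0.0520 and -1.29 ± 0.0991 (SE, n = 6 per group). LHX2 and PTN are also known from progenitors, whose list fell. Of 26 genes of deep-layer and corticofugal neurons, 5 rose, 8 fell and 13 did not pass, with 5 higher and 8 lower adjusted over the list alone. The list as a whole did not pass (adjusted p = 0.116, camera, median -0.02). LMO3, KCNK2, SLA and ETV1 fell, with log2 fold changes of -0.73 ± 0.0525, -1.13 ± 0.0932, -0.73 ± 0.0609 and -1.02 ± 0.0872. Of regulators chosen after their values were seen, BCL11B rose by 0.58 ± 0.0605, whereas FEZF2 had a value of 0.26 (adjusted p = 0.272, edgeR's quasi-likelihood test) and TBR1 of 0.05 (adjusted p = 0.601).

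The subplate is a transient layer of early-born neurons. Of 19 subplate genes, 11 rose, 4 fell and 4 did not pass, with 11 higher and 4 lower adjusted over the list alone, and the list did not pass as a whole (median 0.33, adjusted p = 0.328, camera). The nuclear receptor NR4A2 rose by 0.91 ± 0.0688 on the log2 scale (SE, n = 6 per group) and the synaptic vesicle protein SV2B by 0.70 ± 0.0965. MOXD1, which the radial glia list also holds, fell by 2.11, and the adrenergic receptor ADRA2A fell by 1.07 ± 0.0938. Of 13 genes of intermediate progenitors, 2 rose and 4 fell, with 2 higher and 4 lower adjusted over the list alone, and the list did not pass (median -0.08, adjusted p = 0.464, camera). ELAVL2 and RASGRP1 rose by 0.45 and 0.75, and SMOC1 and TMEM158 fell (-1.70 and -1.23). Of 27 genes found in neurons in general, 10 rose, 5 fell and 12 did not pass, with 10 higher and 5 lower adjusted over the list alone (median 0.05, adjusted p = 0.670, camera). NEUROD6, a transcription factor of excitatory neurons, fell by 0.94 ± 0.0768, SLA fell by 0.73 and the cytoskeletal protein DPYSL3 fell by 0.29. The RNA-binding protein CELF4 rose by 0.52.

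Synaptic genes rose by small amounts. Of 68 synapse genes, 30 rose, 5 fell and 33 did not pass, with 30 higher and 5 lower adjusted over the list alone. Their median was 0.14 (adjusted p = 8.23e-05, camera, and adjusted p = 0.0209 with an estimated correlation). The vesicle fusion protein SNAP25 rose by 0.71 ± 0.0607 on the log2 scale (SE, n = 6 per group), the neurexin NRXN3 by 0.67 ± 0.0631, synaptophysin (SYP) by 0.52 ± 0.0510 and SHISA9 by 0.66 ± 0.0683. Of 41 neurotransmitter receptor genes, 18 rose and 4 fell, with 19 higher and 6 lower adjusted over the list alone. Their median was 0.10 (adjusted p = 0.00879, camera, and adjusted p = 0.0370 with an estimated correlation). The glutamate receptor genes GRIK2 and GRIA1 rose by 0.70 and 0.46 and the cannabinoid receptor gene CNR1 by 0.29, while the GABA receptor subunit GABRA4 fell by 0.65. Voltage-gated ion channel genes did not pass as a list (median 0.09, adjusted p = 0.132, camera). Of 42 tested, 11 rose and 5 fell, with 16 higher and 6 lower adjusted over the list alone. The potassium channels KCNA1 and KCNC2 rose by 1.28 and 0.67, and the sodium channel SCN1A and the potassium channel KCNJ6 fell (-1.58 and -0.72). With offsets for GC content and length, an alternative chosen after seeing the data, this list passed (adjusted p = 0.0481, camera). Of 63 axon guidance and cell adhesion genes, 15 rose and 16 fell, with 16 higher and 17 lower adjusted over the list alone (median 0.01, adjusted p = 0.537, camera). Besides ROBO2 and CNTNAP2, DSCAM rose by 0.78, and the cadherin CDH4 fell by 0.75. The interneuron genes were higher and the progenitor genes lower in the same libraries, with the medians given above.

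Among signalling pathways, NOTCH genes fell. Of 19 NOTCH pathway genes, 10 fell, 1 rose and 8 did not pass, with 1 higher and 10 lower adjusted over the list alone. Their median was -0.35 (adjusted p = 7.41e-08, camera, and adjusted p = 0.0142 with an estimated correlation). The receptors NOTCH1, NOTCH2 and NOTCH3 fell, with log2 fold changes of -2.56 ± 0.123, -2.17 ± 0.0969 and -2.08 ± 0.175 (SE, n = 6 per group), and the target gene HES1 fell by 1.56 ± 0.195. All 4 are also in the radial glia list, and reads of NOTCH2 are uncertain because near-identical NOTCH2NL copies exist. The gene that rose was MAML3, a coactivator, at 0.60, named after its value was seen. Of 21 genes of the BMP and TGF beta pathways, 10 fell and 2 rose, with 2 higher and 11 lower adjusted over the list alone. Their median was -0.22 (adjusted p = 2.05e-05, camera, and adjusted p = 0.0142 with an estimated correlation). FSTL1, INHBB, BMP7 and the receptor TGFBR1 fell, with log2 fold changes of -2.32 ± 0.101, -1.30 ± 0.136, -1.53 ± 0.168 and -0.63 ± 0.0699. WNT pathway genes did not pass as a list (median -0.05, adjusted p = 0.0619, camera), with 4 of 34 higher and 13 lower and 5 higher and 13 lower adjusted over the list alone. This call depended on the settings, and so did the median, for example -0.171 without SOX5 replicate 6 and -0.0792 without SOX5 replicate 4. With all libraries kept, the list passed without a filter on low counts (adjusted p = 0.0220, camera), with at least 1 CPM in at least 6 libraries (0.0215) and on the deposited RPKM values (0.0171 to 0.0173). It also passed without 3 libraries far from their group (0.0169), an alternative chosen after seeing the data, and when any of 9 single libraries was left out. The adjusted p with camera was 0.0457, 0.0432 or 0.0297 without GFP control replicate 1, 2 or 5, and 0.0158, 0.0149, 0.0170, 0.0241, 0.0176 or 0.0274 without SOX5 replicate 1, 2, 3, 4, 5 or 6. SFRP1, FZD8 and TCF7L2 fell (-1.24, -1.92 and -1.62), and WLS, which carries WNT proteins to the cell surface, rose by 0.56.

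SOX5 acts with SOX6 and SOX9 in cartilage, and genes of that programme and of the SOX family were also examined. Of 8 other SOX genes, 2 rose and 4 fell, with 2 higher and 4 lower adjusted over the list alone (median -0.27, adjusted p = 0.00737, camera, and adjusted p = 0.0613 with an estimated correlation). SOX9, SOX21 and SOX8 fell, with log2 fold changes of -1.36 ± 0.0926, -2.81 ± 0.205 and -1.47 ± 0.168 (SE, n = 6 per group), and SOX1 rose by 0.59 ± 0.0696. With limma-voom the SOX list no longer passed either (adjusted p = 0.130, camera). Of 10 cartilage programme genes, 1 rose and 5 fell, with 1 higher and 6 lower adjusted over the list alone (median -0.42, adjusted p = 0.00253, camera, and adjusted p = 0.0890 with an estimated correlation). Besides SOX9, SOX6 and CHST11 fell (-0.56 and -0.26). SOX9 is also in the radial glia list and SOX8 in the oligodendrocyte lineage list, and both of those lists fell. CHST11 missed the threshold with offsets for GC content and length (adjusted p = 0.0507, edgeR's quasi-likelihood test).

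Markers of other cell types that such cultures can hold were tested in the same way. Of 8 endothelial and pericyte genes, 5 fell and 1 rose, with 1 higher and 5 lower adjusted over the list alone. Their median was -0.88 (adjusted p = 0.0101, camera, and adjusted p = 0.0370 with an estimated correlation). On the deposited RPKM values the list no longer passed (adjusted p = 0.0754 to 0.0766, camera). NOTCH3, ABCC9 and PDGFRB, a pericyte receptor, fell (log2 fold changes of -2.08, -2.13 and -2.08), and the efflux pump ABCB1 rose by 1.15. Of 10 fibroblast and mesenchyme genes, 4 rose and 3 fell, with 4 higher and 3 lower adjusted over the list alone (median 0.16, adjusted p = 0.0764, camera). Besides IGFBP5, the matrix protein FBN1 rose by 0.69, and PDGFRB and COL5A2 fell (-2.08 and -0.70). Of 24 microglia and macrophage genes, 1 was tested, the secreted phosphoprotein SPP1, which rose by 1.48 ± 0.131 (SE, n = 6 per group) and passed over all genes (adjusted p = 7.62e-12, edgeR's quasi-likelihood test) and adjusted over the list alone. With 1 gene it says nothing of the list.

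Genes of the interferon response were lower. Of 22 tested, 13 fell and 9 did not pass, with 0 higher and 13 lower adjusted over the list alone. The list median was -0.83 (adjusted p = 5.16e-08, camera, and adjusted p = 0.0370 with an estimated correlation). The antiviral factor TRIM22 fell by 2.23 ± 0.164 on the log2 scale (SE, n = 6 per group), and PARP14 and SAMD9L fell with log2 fold changes of -2.11 ± 0.188 and -2.37 ± 0.255. B2M, a subunit of the antigen-presenting complex, fell by 1.17 ± 0.0925. The radial glia and astrocyte lists were lower in the same libraries, with medians of -1.35 and -1.17. A list of 63 autism risk genes had 11 members higher, 12 lower and 40 not past the threshold, with 11 higher and 13 lower adjusted over the list alone, and did not pass as a list (adjusted p = 0.802, camera). Its median was 0.00037 and its mean was -0.0103, so they differ in sign. Besides CNTNAP2 and DSCAM, the scaffold protein ERBIN fell by 0.53, and the transcription factor TCF7L2 fell by 1.62.

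Of the 32 lists with more than 1 gene tested, 19 passed with camera's preset correlation and 14 of these calls held with an estimated correlation, among them those of the radial glia, cell cycle, astrocyte, oligodendrocyte lineage, interneuron, upper-layer, synapse, receptor, NOTCH, BMP and interferon lists. With the estimated correlation the adjusted p-values of these 14 lists in camera were larger, between 3.91e-05 and 0.0370. The evenness of coverage along transcripts was compared between the groups and did not pass after adjustment. With 6 libraries per group, a single metric could not pass over 30 metrics whatever its values. The median ratio of coverage at the 5' end to that at the 3' end was 0.525 ± 0.0515 in the SOX5 libraries and 0.455 ± 0.0390 in the controls (SD, n = 6 per group, two-sided exact permutation p = 0.0173, adjusted p = 0.260 over 30 metrics). With this ratio as a covariate, an alternative chosen after seeing the data, 1213 genes were higher and 1418 were lower.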

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

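The comparison of sequencing metrics between the groups was a test chosen after seeing the data. In 268 groups of 6 libraries (each named gene in each group, and the total counts), 15 had a library far from the others by Dixon's criterion. Chance gives about 5% of groups, 13.4 here. Of the 14 gene values, 4 were in GFP control replicate 3 and 3 in SOX5 replicate 4.

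LRP1B stood at 127.5 CPM in GFP control replicate 3 (others 121.6 to 123 CPM) and at 257.3 CPM in SOX5 replicate 4 (others 227.3 to 238 CPM). TRPM8 had only 7 reads over all controls, so its flag rests on a few reads. It stood at 0.8459 CPM in GFP control replicate 3, where the others lay between 0 and 0.2245 CPM. HES1 and BMP7 were at 18.61 and 21.99 CPM in that library, above 13.73 and 15.94 CPM in the next highest controls. NOTCH1 was at 81.0 CPM in GFP control replicate 4, with the others at 57.72 to 64.5 CPM. SYP was at 200.9 CPM in GFP control replicate 5, FZD8 at 16.63 CPM in GFP control replicate 2 and WLS at 41.42 CPM in GFP control replicate 6, each below the other controls. POU3F2 was at 232.7 CPM in SOX5 replicate 4, above the others at 197.3 to 200 CPM, and FOSL2 was at 77.57 CPM in the same library, below the others at 93.55 to 102.2 CPM. SOX8 was at 3.291 CPM in SOX5 replicate 2, INHBB at 11.36 CPM in SOX5 replicate 3 and ERBIN at 83.2 CPM in SOX5 replicate 1. The total count of GFP control replicate 6 was 3144776, against 4441930 to 4701195 in the other controls.

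Among the sequencing metrics, the rate of insertions and deletions in aligned reads was 0.0005505 on average in the SOX5 libraries and between 0.000498 and 0.000532 in the controls, so that all 6 SOX5 libraries were higher. The two-sided exact permutation p was 0.00216, the smallest that 6 against 6 allow, and it was 0.0649 after adjustment over 30 metrics. By these exact tests 3 of the 30 metrics had an unadjusted p under 0.05 and 0 passed after adjustment. A single metric could not pass even at the smallest p, so this does not show that the libraries were alike in quality.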

How the results depend on the processing

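The 5' to 3' coverage covariate, the authors' components, the GC and length offsets, the unconverted log2 values and the fit without 3 libraries were tests chosen after seeing the data. Of the counts of called genes, 1 moved by over 1.5 times: 1213 genes were higher with the 5' to 3' coverage ratio as a covariate, against 1825 without it, and 1008 were called in both. The cause was not tested. The group means of the ratio were 0.525 and 0.455, so the covariate and the group share part of their variation. In the alternatives that keep all libraries or leave out 3, the number of higher genes lay between 1213 and 2309 and that of lower genes between 1418 and 2039. With 1 library left out, 1547 to 1962 genes were higher and 1702 to 1935 lower. Without the 3 libraries far from their group, 1686 were higher and 1840 lower. The SOX5 log2 fold change lay between 4.15 and 4.37 in every alternative.

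Replicate numbers are shared by the groups, and a check of whether they pair the samples was mixed, so a pairing is not ruled out. Over the 5000 most abundant genes, 2 of 6 same-numbered pairs had correlated deviations over 0.1 (0.447 and 0.241), and 2 of 6 controls correlated best with their own number. With the replicate number as a block, 1848 genes were higher and 1843 lower. The block changed the call of MT-ND3 (0.55, adjusted p = 0.0134 in edgeR's quasi-likelihood test) and of no other named gene or list.

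The median log2 fold change of all genes was 0.0052 with TMM, -0.0187 with upper-quartile scaling and 0.0331 with GC and length offsets. Higher genes made up 49.9%, 44.4% and 59.0% of calls in these fits, and upper-quartile scaling gave 1627 higher and 2039 lower genes. For named genes, 3688 values kept direction and call, 4 lost and 1 gained a call, and 3 turned. For lists, 938 kept the test's direction and call, 14 lost and 23 gained a call, and 15 turned. All 18 that turned were uncalled before and after, and the cause was not tested. With the 5' to 3' covariate, MT-ND3, MT-ND1 and MT-ND5 turned to -0.0936, -0.125 and -0.0991 (log2 fold change), and the medians of the neuron, cholesterol synthesis, autism and mitochondrially encoded lists were -0.0367, 0.0545, -0.0365 and -0.138. The autism list also turned in limma-voom (median -0.0091). The mitochondrially encoded list (median 0.0330) also turned with the authors' components (0.0365), with GC and length offsets (-0.0422) and in fry (same median). With single libraries left out it turned in 5 fits, and the cholesterol synthesis list turned in 2. Over all fits with 1 library left out, the medians ranged from -0.103 to 0.226 (mitochondrially encoded) and from -0.0615 to -0.0000108 (cholesterol synthesis). A list turned when the direction of its test did, so its median could keep its sign. Fry called the deep-layer, subplate, intermediate progenitor, voltage-gated channel, fibroblast, WNT and p53 lists in addition (adjusted p = 2.79e-06 to 0.0479). Per-sample counts and a batch factor were not run. Depth limits what can be said of genes near 1 CPM, such as TRPM8 with 7 control reads in total.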

Other observations

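Tests of the patterns weighed here were chosen after the result was seen, except the count of splits of the libraries, for which the prediction was written before the test was run. Genes of the immediate early response, which neuronal activity and growth factors induce, were higher. Of 24 tested, 12 rose and 2 fell, with 14 higher and 2 lower adjusted over the list alone. Their median was 0.42 (adjusted p = 2.52e-05, camera, and adjusted p = 0.0158 with an estimated correlation). FOSL2 rose by 1.10 ± 0.0765 on the log2 scale (SE, n = 6 per group), JUN by 0.67 ± 0.0485, the neurotrophin BDNF by 0.78 ± 0.0636 and JUND by 0.42 ± 0.0725. In the same libraries the interneuron list was higher and the radial glia and astrocyte lists were lower (medians of 0.90, -1.35 and -1.17). Of 30 genes of the unfolded protein response, 12 rose and 3 fell, with 12 higher and 4 lower adjusted over the list alone (median 0.23, adjusted p = 0.0256, camera, and adjusted p = 0.140 with an estimated correlation). This list also missed the threshold with the authors' components, the 5' to 3' coverage ratio or GC and length offsets in the fit (adjusted p = 0.0531, 0.0578 and 0.0661, camera). PPP1R15A rose by 0.71, DNAJB11 by 0.47, HYOU1 by 0.35 and ATF4 by 0.33. Of 27 p53 target genes, 4 rose and 8 fell, with 4 higher and 9 lower adjusted over the list alone (median -0.06, adjusted p = 0.802, camera). BBC3, a cell death gene, rose by 0.92, and TP53INP1, POLH and ZMAT3 fell (-0.42, -0.49 and -0.31). TP53INP1 missed the threshold with the 5' to 3' coverage ratio as a covariate (adjusted p = 0.0526, edgeR's quasi-likelihood test).

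Protein synthesis and energy metabolism were covered by 5 further lists. Of 73 cytosolic ribosomal protein genes, 25 rose and 1 fell, with 25 higher and 1 lower adjusted over the list alone (median 0.20, adjusted p = 3.59e-05, camera, and adjusted p = 0.421 with an estimated correlation). RPL8, RPL3, RPL23 and RPS9 rose by 0.55, 0.56, 0.72 and 0.55 on the log2 scale, with uncertain reads because of processed pseudogenes. Of 57 nuclear-encoded respiratory chain genes, 15 rose and 2 fell, with 16 higher and 2 lower adjusted over the list alone (median 0.17, adjusted p = 0.0111, camera, and adjusted p = 0.421 with an estimated correlation). It missed the threshold with the 5' to 3' coverage ratio or GC and length offsets in the fit (adjusted p = 0.0608 and 0.106, camera). COX4I1 and ATP5F1B rose by 0.54 and 0.36. Of 13 mitochondrially encoded genes, 1 fell, MT-CO1 by 0.23 ± 0.0462 (SE, n = 6 per group), and the rest did not pass (median 0.03, adjusted p = 0.925, camera, with fry in the opposite direction), with 0 higher and 1 lower adjusted over the list alone. Hypoxia and glycolysis genes (7 of 31 higher and 3 lower, with 7 higher and 3 lower adjusted over the list alone, median 0.08) and cholesterol synthesis genes (3 of 23 higher and 4 lower, with 5 higher and 4 lower adjusted over the list alone, median -0.04) did not pass as lists (adjusted p = 0.575 and 0.802, camera). LDHA rose by 0.29, and the cholesterol enzymes LSS, HMGCS1 and MSMO1 fell (-0.58, -0.28 and -0.43).

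Among the splits drawn, no chance assignment of these 12 libraries to the groups gave as many called genes as the real one. Of 100 splits of the 12 libraries into groups of 6, drawn from 462 and with the real split included, 1 gave as many genes. That is the real split itself, and 1 in 100 is the smallest share this draw allows. The real split gave 3657 and the highest of the others 567. Every other split mixes libraries that the first principal component separates by group, so lower counts there could be foreseen. If the libraries of a group come from 1 culture, the split counts show only that the sets of libraries differ, and a chance difference between cultures is not excluded.

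The radial glia, G2 and M phase, astrocyte and oligodendrocyte lineage lists were lower together, with a median of -1.37 over 107 members, 82.2% of them called lower. With the 5' to 3' coverage ratio as a covariate the median was -1.3474 and 78.5% were called lower, which argues against uneven coverage as the whole source. With GC and length offsets the median was -1.3443 and 81.3% were called lower, which argues against that bias too. As a hypothesis, SOX5 may lower the number of progenitor and glial cells in these cultures or the level of their genes per cell. RNA from whole cultures leaves both open, and neither was tested.

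The interneuron list, of whose 24 genes another list holds 1, rose with a median of 0.90, and a candidate explanation is that fewer progenitors and glia leave a larger share of every neuron type. The median of the interneuron list exceeded that of 48 genes of the deep-layer and upper-layer lists by 0.99374 log2 units (permutation p = 1e-05 over genes). That p is the smallest that 100000 permutations can give, with genes not independent. Both medians were known when the comparison was chosen, so the p adds no support. Of those 48 genes, 17 were called lower and 5 higher, but some, such as PTN and LHX2, are also known from progenitors. The 27 genes found in neurons in general had a median of 0.05, with 10 higher and 5 lower. Other neuronal lists leaned higher, but by less than the interneuron list. Of 68 synapse genes 30 were higher and 5 lower (median 0.14), and of 41 receptor genes 18 were higher and 4 lower (median 0.10). Of 19 subplate genes 11 were higher and 4 lower (median 0.33). A rise of every neuron type alike would raise all these lists alike, so the medians argue against it as the whole source. A smaller rise shared by neurons is not excluded. With GC and length offsets the interneuron median was 0.91291 and 100% of members were called higher. In the main fit without the DLX genes the median was 0.89703. All 24 genes were higher, so leaving out a few could hardly move the median. It shows only that the rise was not confined to the DLX genes. Whether the share of interneurons or the expression of their genes per cell was higher was not tested, and counts from whole cultures cannot separate these.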
